A study of Caenorhabditis elegans with 22 samples.

How the data were processed

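Whole adult Caenorhabditis elegans were profiled as 22 samples, of which 8 were small RNA libraries, 8 were total RNA libraries and 6 were mRNA libraries. Per the labels' protocols, starved L1 larvae were plated and grown for 71 h at 20 °C, and the animals were young adults carrying embryos, 70 h after L1 arrest. Small RNA of 18 to 28 nt was selected on a gel and treated with a 5′ polyphosphatase before the adaptors were ligated, per the labels' protocols. Ribosomal RNA was depleted from the total RNA libraries, and the mRNA libraries were made from polyadenylated RNA with a strand-specific kit, per the labels' protocols. The small RNA and total RNA series each held 2 libraries of wild type, adr-1;adr-2, eri-6 and adr-1 eri-6;adr-2. The mRNA series held 1 library of wild type and 1 of adr-1 eri-6;adr-2 on each of control, drh-1 and nrde-3 RNAi. Samples were grouped by the genotype and the RNAi food that their labels give. The wild-type and adr-1;adr-2 small RNA libraries are labelled with different strains within the genotype, so their spread also holds differences of strain. For the other groups nothing in the labels shows the libraries of 1 genotype as separate cultures. The p-values therefore measure the spread between these samples.

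The strain labels differ inside groups. Wild-type small RNA replicate 1 was strain GR1831, which carries the transgene mgIs30, and replicate 2 was N2. The adr-1;adr-2 small RNA libraries came from strains BB4 and BB21, which are labelled with different alleles. The adr-1 eri-6;adr-2 strain GR1744 is labelled with the alleles gv6 and gv42, while the adr-1;adr-2 total RNA libraries are labelled with strain BB4 but with the alleles tm668 and ok735. The small RNA label of BB4 gives gv6 and gv42, so by the strain name the total RNA alleles would equal those of GR1744, and by the allele labels they would differ.

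Per the submitters' processing notes, Trim Galore, BWA, featureCounts, DESeq2, TopHat2, Cufflinks and Cuffdiff were used with genome build WBcel235. Their versions, settings and gene annotation are not given in the sources used here. The small RNA values are a signal per gene and library that the authors normalised before they deposited it. Every value was a whole number of reads multiplied by 1 factor per library, within 0.01 read for 100% of the values, so the reads could be recovered. The recovered depths were 32303754 and 15417839 reads for adr-1;adr-2, 29683818 and 10904105 reads for eri-6, and 25690179 and 12446099 reads for wild type. The wild-type reads were equal for 100% of genes in the adr-1;adr-2 and eri-6 tables, so both comparisons use the same wild-type libraries. The small RNA table of adr-1 eri-6;adr-2 holds 381 genes that the authors selected from these libraries, so its depth is unknown and its calls are not independent evidence. Of the 24342 genes with a mean of at least 10 reads over the 6 libraries of the other tables, 4427 had the same reads in every library as another gene, which are most simply copies whose reads cannot be told apart.

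The total RNA values are FPKM that the authors deposited as 1 value per genotype, with a lower and an upper bound, over both replicates. The level of those bounds is not given in the sources used here. The mRNA values are FPKM that the authors deposited as 1 value per library, scaled separately for the drh-1 and nrde-3 RNAi tables, in which the control libraries differed by a median ratio of 1.08 in wild type and 1.09 in adr-1 eri-6;adr-2. The depth of the total RNA and mRNA libraries is unknown. Of 36234 entries in the total RNA table and 37425 in each mRNA table, 321 and 344 were left out because 1 gene ID had more than 1 entry, which removed adr-1 and adr-2 from total RNA. Short loci weighed heavily on the total RNA values, since loci under 200 bp held between 23.5% and 27.2% of the FPKM sum. Of the 46780 gene IDs in the small RNA tables, 43818 were named from a reference table of build WBcel235, 2737 were named from the deposited FPKM tables and 225 had no name.

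Each small RNA table was analysed alone in R 4.3.3 with limma 3.58.1 (trend) on log2 of the value plus 1, for genes with a mean of at least 10 over its 4 libraries, with Benjamini-Hochberg adjustment at 0.05. Gene lists of at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, and again with the correlation estimated from the data and with fry. In total RNA a gene was called higher or lower when its deposited bounds did not overlap, because the table holds no q-value. In mRNA a gene was called at a fold of at least 4 on FPKM plus 1, with no test. List medians in FPKM tables used genes of at least 1 FPKM and were placed as percentiles among 10000 random lists of the same size, matched on mean FPKM in 20 bins; they describe these libraries and are not tests. The tools edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.

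Named genes followed a rule chosen before the data were examined, as were the tests, the gene lists and most alternatives. It names adr-1, adr-2, eri-6, eri-7, drh-1 and nrde-3, the 10 largest rises and falls among called genes, and up to 4 members of each list described. For small RNA both mutant libraries had to lie beyond both wild-type libraries with a mean of at least 50 in the higher group. No gene passed the limma test in the adr-1;adr-2 and eri-6 tables, and in the FPKM tables the rule named mostly short loci listed at 0 in 1 condition. A further rule was therefore added after seeing the data. It names small RNA genes with every mutant library at least 4-fold above or below every wild-type library, and protein-coding genes above 0 in both conditions of the FPKM tables. The comparison of mutant with mutant, the counts of protein-coding genes alone and the sets of separated genes were likewise added after seeing the data.

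The 21 lists held ERGO-1 class siRNA targets, pals genes, other genes of the intracellular pathogen response, RNAi factors, retroelements, piRNA, microRNA, histone, sperm, vitellogenin, collagen, germline, muscle, neuron, intestine, heat shock, unfolded protein response, detoxification, C-type lectin and antimicrobial, ribosomal protein and F-box genes. The retroelement list matched 0 genes by name and gave no result, and 19 of the 20 written ERGO-1 class names matched. The piRNA list had too few members at 1 FPKM for a result in the FPKM tables.

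The methods were tested on simulated data made from the real means. The noise was 1 fixed dispersion for all genes, not estimated from these libraries. Recovery in the real data may therefore be lower, and false calls more frequent. With the difference between replicates 1 and 2 as observed, limma and edgeR without a term for the replicate number each recovered 0 of 100 genes changed 4-fold and 0 of 100 changed 64-fold in both comparisons. DESeq2 recovered 0 of the 4-fold genes, and 98 of the 64-fold genes for adr-1;adr-2 (24851 genes simulated) and 97 for eri-6 (24199 genes). The 4-fold separation rule recovered 8 and 94 for adr-1;adr-2, and 4 and 96 for eri-6, and called 0 unchanged genes. Without that replicate difference limma recovered 97 of the 4-fold genes for adr-1;adr-2 and 98 for eri-6, with 17 and 2 unchanged genes called. In the simulation of percentiles, a planted list of 20 genes shifted by 1 on the log2 scale reached percentile 100.0, and 55% of 100 unshifted lists lay below percentile 50. Alternatives covered pseudocounts, filters, TMM scaling, equal totals, edgeR and DESeq2 on recovered reads, 1 fit of 6 libraries, leaving out each library in turn, set tests and rescaled FPKM.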

Results

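The study profiled RNA from whole day 1 adult worms in which RNA editing or a branch of RNA interference was lost. The adr-1 and adr-2 genes encode the ADAR family of worms, and ADR-2 converts adenosine to inosine in double-stranded RNA. The eri-6 and eri-7 genes are joined by trans-splicing into a helicase that the ERGO-1 Argonaute pathway needs to make 26G small interfering RNAs (siRNAs) from a small set of mostly duplicated genes. The title of the series ties both pathways to the silencing of endogenous viral elements and retrotransposons. Small RNA and total RNA were measured in wild type, adr-1;adr-2, eri-6 and adr-1 eri-6;adr-2, with 2 libraries of each. Messenger RNA was measured in wild type and adr-1 eri-6;adr-2 fed bacteria for control, drh-1 or nrde-3 RNAi, with 1 library per condition. DRH-1 is a helicase related to the antiviral sensor RIG-I, and NRDE-3 is an Argonaute that carries siRNAs into the nucleus.

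Small RNA depth was 32303754 and 15417839 reads for adr-1;adr-2, 29683818 and 10904105 for eri-6, and 25690179 and 12446099 for wild type. Replicates 1 and 2 differed in composition in every genotype. MicroRNAs, which are cut from hairpin precursors, took 39.8% of reads in adr-1;adr-2 replicate 1 and 24.7% in replicate 2. The same shares were 39.3% and 23.5% in wild type and 39.1% and 21.3% in eri-6. Protein-coding genes, the main templates of secondary siRNAs, took 38.4% and 53.7% in adr-1;adr-2, 39.4% and 55.7% in wild type, and 36.5% and 57.6% in eri-6. This difference between replicates was larger than that between genotypes. Lists that passed are therefore also given within each replicate number. Those values use 1 joint TMM scaling of the 6 libraries and its own filter on low genes. The list medians use the deposited scaling of each table, so a median can lie outside both replicate values. A fit without 1 library holds unequal numbers of replicates 1 and 2, so what changes in it mixes that difference with genotype and is no measure of stability.

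The eri-6 comparison asked which small RNAs need the ERI-6/7 helicase. ERGO-1 class genes lost nearly all of their small RNA signal in the eri-6 mutant. The pseudogene W04B5.1 (WBGene00021018, III:2428204-2429430) had 25.0 ± 15.2 normalised reads against 6698 ± 3745 in wild type (mean ± SD, n = 2 each), a log2 fold of −8.02 ± 0.84 (SE). C36A4.11 (WBGene00044167, III:3840579-3841248) had 20.6 ± 10.1 against 4726 ± 1744, a log2 fold of −7.81 ± 0.78. The duplicated neighbours F55C9.5 and F55C9.3 lay at −6.83 and −6.67. The median over the 19 ERGO-1 class genes was −6.13, and it was −6.62 within replicate 1 and −5.58 within replicate 2. The camera test gave adjusted p = 1.33e-101 for this list, and adjusted p = 0.389 with an estimated correlation. Of its members, 17 were lower when adjusted over the list alone and 0 when adjusted over all genes.

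**Figure D1:**
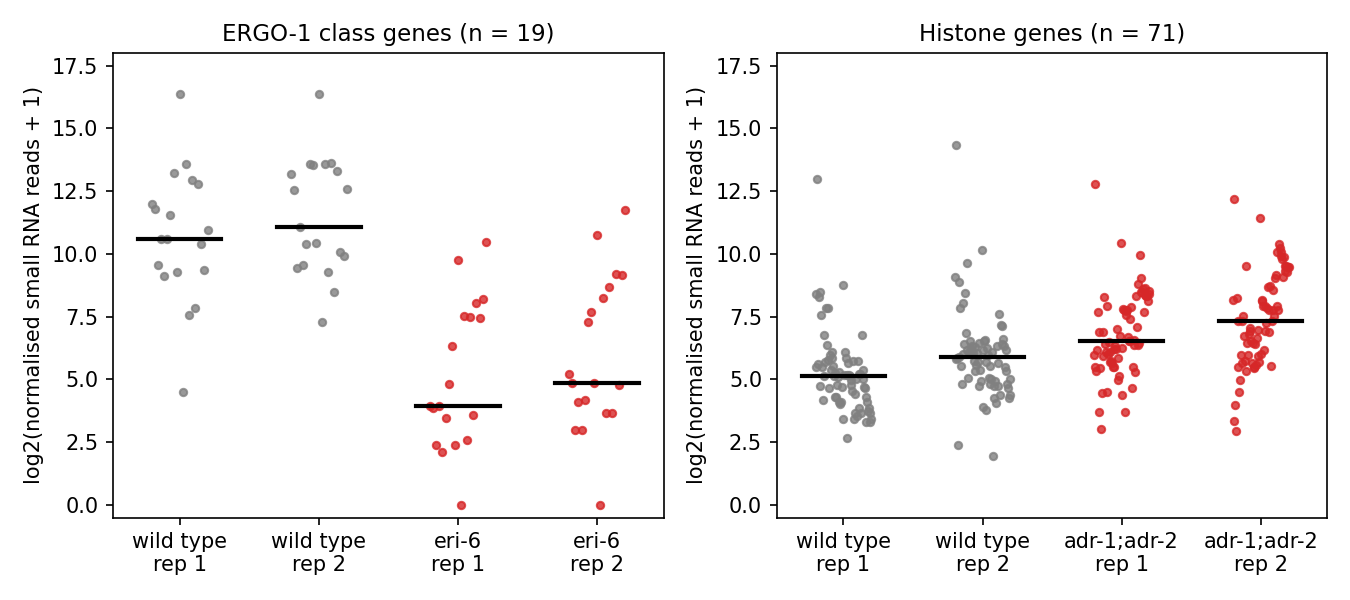
Normalised small RNA reads per gene on a log2 scale (each value plus 1) in each library, for the 19 ERGO-1 class genes in wild type and eri-6 and the 71 histone genes in wild type and adr-1;adr-2. Each point is 1 gene, the position of a point within its column carries no meaning, and bars are medians; the median difference was −6.13 for ERGO-1 class genes and 1.52 for histone genes.

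Single loci outside the written list were also low in eri-6, though noncoding RNAs and pseudogenes were not tested as classes. The intergenic RNA linc-41 (WBGene00219689, IV:4241224-4241765) had 1.84 ± 0.96 normalised reads against 1410.0 ± 195 in wild type, and linc-45 (WBGene00219661, III:3151809-3152607) had 6.25 ± 0.67 against 2157 ± 428. The pseudogene F56D6.16 had a log2 fold of −8.08, Y36E3A.2 of −8.65 and K06B9.6 of −7.95. A piRNA locus, 21ur-9823, was listed at 0 in both eri-6 libraries against 360 ± 4.36 in wild type. The microRNA mir-262 had a log2 fold of −7.83, mir-8199 of −6.25 and mir-260 of −5.40, and these 3 were lower when adjusted over the list of microRNA genes alone. By contrast mltn-3 (WBGene00012199, II:13916340-13919677) and its relative mltn-4 were higher, at 5.36 and 3.99. Other genes on the high side were T28F2.1 at 5.13, F44E5.2 at 4.88, the collagen gene col-87 at 4.51, C45G7.13 at 4.44, cdh-10 at 3.86, B0507.1 at 3.70 and C55C3.7 at 3.70. The pals-27 gene (WBGene00007132, III:4381643-4384166), from a family that responds to intracellular pathogens, had 281 ± 99.3 normalised reads against 14.1 ± 3.85, a log2 fold of 4.20. Its relatives pals-25 and pals-22 lay at 2.55 and 1.66.

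The limma test called 0 genes higher and 0 lower among the 23380 genes tested in eri-6, with a smallest adjusted p = 0.0680. On simulated data with the observed difference between replicates 1 and 2 this test recovered 0 of 100 genes changed 64-fold in either comparison, so the lack of calls does not mean that no gene differed. At an unadjusted p under 0.05 there were 237 genes, edgeR called 0 with 247 unadjusted, and DESeq2 called 15 higher and 125 lower. With a term for the replicate number, limma called 8 genes higher and 98 lower in eri-6, and 0 and 0 in adr-1;adr-2. The labels do not state that replicate numbers pair the libraries. The rule of every mutant library at least 4-fold beyond every wild-type library, added after seeing the data, found 20 genes higher and 136 lower, including linc-41, W04B5.1, C36A4.11, mltn-3 and pals-27. A crossed split, which puts replicate 1 of one genotype with replicate 2 of the other, gave 16 genes on 1 side and 5 on the other. Its sides do not stand for higher and lower in eri-6, so only the sums compare, 156 genes against 21. The 20 higher genes alone were close in number to the larger side of that split. Leaving out wild-type replicate 1 gave 11 higher and 90 lower genes in limma, leaving out wild-type replicate 2 gave 7 and 71, leaving out eri-6 replicate 1 gave 1 and 42, and leaving out eri-6 replicate 2 gave 0 and 58. The eri-6 and eri-7 loci were themselves covered by small RNA at similar levels, with log2 folds of −0.48 and −0.24, while adr-1, adr-2, drh-1 and nrde-3 lay at −0.24, −0.23, −0.19 and 0.20.

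Other gene classes in eri-6 moved far less than the ERGO-1 class. The piRNA genes, whose 21U RNAs are transcribed in the germline, had a median of 0.65 over 8022 genes (adjusted p = 9.92e-26). Small RNA from ribosomal protein genes, which often reports degraded mRNA, had a median of −0.69 over 78 genes (adjusted p = 8.02e-18). Sperm genes had −0.62 and germline genes −0.29 (adjusted p = 0.00397 for each), RNAi factors −0.23 (adjusted p = 0.00866) and unfolded protein response genes −0.41 (adjusted p = 0.0149). The pals genes passed with a median of 0.16 and a mean of 0.59 over 19 genes (adjusted p = 0.00568), and pals-27 alone was higher when adjusted over the list alone. None of these 7 lists passed with an estimated correlation (adjusted p = 0.918 for each). Sperm genes lay at −1.74 within replicate 1 and 0.60 within replicate 2. The same values were 0.48 and 0.78 for piRNA, −0.50 and −0.77 for ribosomal protein, −0.15 and −0.50 for germline, −0.13 and −0.65 for unfolded protein response and 0.31 and 0.25 for pals genes, and −0.05 and −0.36 for RNAi factors. Without eri-6 replicate 1 the piRNA, germline and RNAi factor lists changed direction (adjusted p = 0.0165, 1.00 and 0.529), and they also did without wild-type replicate 2 (adjusted p = 0.00204, 0.185 and 0.0908). The sperm list changed direction without eri-6 replicate 2 (adjusted p = 0.259) or wild-type replicate 1 (adjusted p = 0.00239). Without wild-type replicate 2 the unfolded protein response list changed direction and the ribosomal list did not pass (adjusted p = 0.450 and 0.933), and without eri-6 replicate 1 the unfolded protein response list did not pass (adjusted p = 0.805). The pals list did not pass without eri-6 replicate 2 (adjusted p = 0.865) or wild-type replicate 1 (adjusted p = 0.991).

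The remaining lists did not pass in eri-6. Medians were −0.13 for microRNA genes (adjusted p = 0.127), −0.13 for C-type lectin genes (adjusted p = 0.184), −0.03 for detoxification genes and −0.04 for muscle genes (adjusted p = 0.327 for each). F-box genes had −0.02 (adjusted p = 0.421), with fbxa-52 lower at −6.07 when adjusted over the list alone. Collagen genes had −0.11, histone genes 0.09, vitellogenin genes 0.24 and neuron genes a median of 0.04 with a mean of −0.16 (adjusted p = 0.580 for each of the 4). Heat shock genes had a median of −0.13 with a mean of 0.02, and intestine genes had −0.15 (adjusted p = 0.732 for each). Without eri-6 replicate 1 collagen, F-box, histone and vitellogenin genes passed on the high side (adjusted p = 0.00294, 0.000451, 9.95e-05 and 0.0138) and microRNA genes on the low side (adjusted p = 1.30e-09). Without wild-type replicate 2 collagen, F-box, histone and heat shock genes passed on the high side (adjusted p = 0.00998, 0.000177, 0.000897 and 0.0213) and microRNA genes on the low side (adjusted p = 0.000110). Without eri-6 replicate 2 collagen, F-box, histone, C-type lectin and detoxification genes passed on the low side (adjusted p = 0.00437, 1.55e-05, 0.0151, 0.00566 and 0.00901). Without wild-type replicate 1 the same 5 classes and heat shock genes did (adjusted p = 0.00760, 2.17e-06, 0.0108, 0.0115, 0.0108 and 0.0176).

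The adr-1;adr-2 comparison asked which small RNAs arise when double-stranded RNA is no longer edited. The neighbouring genes F39E9.1 (WBGene00018194, II:3318302-3320358), a pseudogene, and Y46D2A.2 (WBGene00021590, II:3321130-3323279) carried a dense cover of small RNA against traces in wild type. F39E9.1 had 17009 ± 8537 normalised reads against 77.8 ± 99.96 in wild type (mean ± SD, n = 2 each), a log2 fold of 8.83 ± 1.25 (SE), and Y46D2A.2 lay at 8.56. The peroxisomal transporter gene pmp-2 (WBGene00004059, II:6884040-6887805) had 789 ± 216 against 8.33 ± 4.22, a log2 fold of 6.45 ± 0.96. The F-box genes fbxc-5 and fbxc-3 lay at 6.56 and 5.88, irld-53 at 6.54, the chitinase-like gene chil-22 at 6.40, C25F9.10 at 6.09, T05E12.6 at 5.90 and cst-2 at 5.83. On the low side, the locus of F15D4.5 (WBGene00008862, II:13245376-13247774) had 1805 ± 53.9 normalised reads against 27736 ± 19198, a log2 fold of −3.74 ± 1.00. The piRNA locus 21ur-10492, which lies inside F15D4.5, had −5.08. Other low genes were fezf-1 at −4.71, W09B7.1 at −4.15, F07B7.1 at −4.03, R13H4.5 at −3.75, Y38F2AL.12 at −3.47, fbxa-192 at −3.22 and K09B3.1 at −3.10.

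Small RNA at the mutated genes was lower, with 76.6 ± 12.3 against 474 ± 207 normalised reads for adr-1, a log2 fold of −2.55 ± 0.93, and a log2 fold of −1.47 ± 0.93 for adr-2. The drh-1, eri-6, eri-7 and nrde-3 genes lay at −0.43, −0.33, −0.88 and 0.05. The limma test called 0 genes higher and 0 lower among 23975, with a smallest adjusted p = 0.155. At an unadjusted p under 0.05 there were 324 genes, edgeR called 0 with 463 unadjusted, and DESeq2 called 108 higher and 10 lower. The 4-fold rule, added after seeing the data, found 118 genes higher, among them F39E9.1, Y46D2A.2 and pmp-2, and 17 lower, among them F15D4.5. The crossed split gave 13 and 8, and the split of replicate 1 from replicate 2 gave 1382 and 95. In limma, leaving out adr-1;adr-2 replicate 1 gave 30 higher and 49 lower genes, leaving out adr-1;adr-2 replicate 2 gave 3 and 0, leaving out wild-type replicate 1 gave 16 and 10, and leaving out wild-type replicate 2 gave 32 and 4.

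Histone genes stood out among the lists in adr-1;adr-2. Replication-dependent histone mRNAs end in a stem-loop in place of a poly(A) tail. The median over 71 histone genes was 1.52, with 1.69 within replicate 1 and 1.36 within replicate 2. The camera test gave adjusted p = 1.53e-30 for the list, and adjusted p = 0.721 with an estimated correlation. Adjusted over the list alone 13 members were higher, led by his-19 at 5.09, his-21 at 4.78, his-7 at 4.74 and his-51 at 4.68, while adjusted over all genes there were 0. In eri-6 the histone median was 0.09. Compared directly, in a test added after seeing the data, eri-6 lay below adr-1;adr-2 by a median of −1.30 over these genes (adjusted p = 1.15e-29, and adjusted p = 0.564 with an estimated correlation), with 0 single histone genes called by limma.

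The heat shock, vitellogenin, detoxification, C-type lectin, piRNA and microRNA lists also passed on the high side in adr-1;adr-2. Heat shock genes had a median of 1.55 (adjusted p = 0.000273), though 2.46 within replicate 1 and 0.25 within replicate 2. Vitellogenin genes, which encode yolk proteins made in the intestine, had 1.32 (adjusted p = 0.000323), with 1.65 and 0.91 within replicates. Detoxification genes had 0.50 (adjusted p = 0.000103), C-type lectin genes 0.25 (adjusted p = 0.000876), piRNA genes 0.51 (adjusted p = 2.15e-13) and microRNA genes 0.14 (adjusted p = 0.00990). Within replicates 1 and 2 detoxification genes lay at 0.42 and 0.41, C-type lectin genes at 0.46 and 0.32, piRNA genes at 0.11 and 0.98, and microRNA genes at −0.15 and 0.62, in opposite directions. Lower were ribosomal protein genes at −0.77 (adjusted p = 2.87e-14), with −0.19 and −1.20 within replicates. RNAi factors lay at −0.49 (adjusted p = 0.00265), unfolded protein response genes at −0.44 (adjusted p = 0.0123), germline genes at −0.41 (adjusted p = 0.0138) and sperm genes at −0.61 (adjusted p = 0.0219). Their values within replicates 1 and 2 were −0.24 and −0.47 for RNAi factors, −0.18 and −0.76 for unfolded protein response genes, −0.05 and −0.42 for germline genes, and −0.99 and 0 for sperm genes. With an estimated correlation none of these 11 lists passed (adjusted p = 0.721 for heat shock, vitellogenin, detoxification, C-type lectin and ribosomal genes, 0.945 for sperm genes and 0.879 for the others).

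Several of these lists changed in fits without 1 library, and their levels differed between replicates, such as medians of 6.41 and 1.55 for sperm genes in wild-type replicates 1 and 2. Without adr-1;adr-2 replicate 2 the heat shock, vitellogenin, detoxification and C-type lectin lists did not pass (adjusted p = 0.0729, 0.199, 0.777 and 0.418). They also did not pass without wild-type replicate 1 (adjusted p = 0.720, 0.342, 0.375 and 0.375). The piRNA, germline and RNAi factor lists changed direction without adr-1;adr-2 replicate 1 (adjusted p = 0.285, 0.942 and 0.942) and without wild-type replicate 2 (adjusted p = 1.39e-06, 0.186 and 0.186). The sperm list changed direction without adr-1;adr-2 replicate 2 (adjusted p = 6.52e-07) or wild-type replicate 1 (adjusted p = 0.000258). Without wild-type replicate 2 the microRNA and unfolded protein response lists changed direction and the ribosomal list did not pass (adjusted p = 0.672, 0.625 and 0.672). Without adr-1;adr-2 replicate 1 the microRNA and unfolded protein response lists did not pass (adjusted p = 0.760 and 0.757).

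ERGO-1 class genes did not pass in adr-1;adr-2, with a median of 0.02 (adjusted p = 0.805), and lay at −0.45 within replicate 1 and 0.61 within replicate 2, in opposite directions. Without adr-1;adr-2 replicate 2 the list lay on the low side (adjusted p = 9.89e-05) and without adr-1;adr-2 replicate 1 or wild-type replicate 2 on the high side (adjusted p = 0.000254 and 0.0325). Intestine genes had 0.18 and muscle genes −0.17 (adjusted p = 0.805 for each). Collagen genes had −0.18 (adjusted p = 0.137), neuron genes 0.03 (adjusted p = 0.220) and other intracellular pathogen response genes a median of −0.22 with a mean of 0.83 (adjusted p = 0.147). The pals genes had a median of −0.14 with a mean of 0.08 (adjusted p = 0.751). F-box genes had a median of −0.13 with a mean of 0.03 (adjusted p = 0.464), and 5 of them, all on the high side and including fbxc-5 and fbxc-3, passed when adjusted over the list alone. Collagen and F-box genes passed on the low side without adr-1;adr-2 replicate 2 (adjusted p = 0.00448 and 0.000914) and without wild-type replicate 1 (adjusted p = 0.00206 and 0.000118). Without wild-type replicate 2 the collagen, F-box, pathogen response and pals lists passed on the high side (adjusted p = 0.0402, 6.38e-06, 0.0479 and 0.0402).

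For adr-1 eri-6;adr-2 the small RNA was given only for genes that the authors had selected on these samples. The calls that follow are therefore not independent evidence. The selected genes joined the patterns of both other mutants. On the low side were linc-41 at −9.58, linc-17 at −8.63, F56D6.16 at −8.23, Y36E3A.2 at −8.04, K02E2.6 at −7.36, F56D6.17 at −7.23, linc-15 at −7.07, F55C9.3 at −7.04, ZK384.7 at −7.02 and F55C9.5 at −6.97. On the high side were F39E9.1 at 8.16, Y46D2A.2 at 7.83, Y105C5A.24 at 6.80, chil-22 at 6.32, pmp-2 at 6.11, T05E12.6 at 6.01, gst-27 at 5.65, rcd-1 at 5.61, tag-234 at 5.40 and pals-27 at 5.25. Among the selected genes 280 were higher and 101 lower than wild type. Both mutant libraries lay beyond both wild-type libraries for 275 higher and 89 lower genes, a separation that the selection on these libraries itself favours. Of 374 genes tested, 245 passed as higher and 64 as lower. Without adr-1 eri-6;adr-2 replicate 2 or wild-type replicate 1, 132 and 127 passed as higher.

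Gene classes were thinly represented among the selected genes. ERGO-1 class genes numbered 6, all lower and all past 0.05, with a median of −6.58. Histone genes numbered 7, all higher, with a median of 1.68 and 4 past 0.05. Vitellogenin genes numbered 5, all higher, with a median of 2.11 and 4 past 0.05. Of the 16 C-type lectin and antimicrobial genes 14 were higher and 13 passed, with a median of 2.63, and of the 10 detoxification genes 9 were higher and passed, with a median of 2.75. The pathogen response genes B0507.6 and skr-3, the intestine genes pept-1 and lys-1, the collagen gene col-62 at 4.64 and pals-27 were higher and past 0.05. The piRNA loci 21ur-10492 and 21ur-10687, the muscle gene unc-54 at −2.58 and rpl-11.2 at −1.76 were lower and past 0.05. Of 4 F-box genes 1 was higher and passed, and of the microRNA genes mir-260 and mir-1831 each direction had 1.

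Both groups of selected genes could be followed in the tables of all genes. The 246 genes selected as higher in adr-1 eri-6;adr-2 had a median log2 fold of 1.81 in adr-1;adr-2 and 0.42 in eri-6. The 100 genes selected as lower had a median of −0.26 in adr-1;adr-2 and −1.99 in eri-6. Compared directly, eri-6 lay below adr-1;adr-2 by a median of −1.36 for the higher genes and −1.98 for the lower genes, while 10000 random lists gave medians between −0.0853 and 0.172 and between −0.0961 and 0.223. Every adr-1;adr-2 library lay above every eri-6 library for 135 of the higher genes and the reverse held for 46. Interchangeable libraries would give 41. For the lower genes every eri-6 library lay below every adr-1;adr-2 library for 54 and above for 16, where they would give 16.7. Replicates 1 and 2 differed in every genotype, so the libraries were not interchangeable, and the 46 and 16 genes cannot be read as chance. Under 1 joint scaling, 51 of the higher genes were 4-fold higher in adr-1;adr-2 and 6 in eri-6. Of the lower genes, 4 were 4-fold lower in adr-1;adr-2 and 35 in eri-6. The shared wild-type libraries favour these counts.

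**Figure D2:**
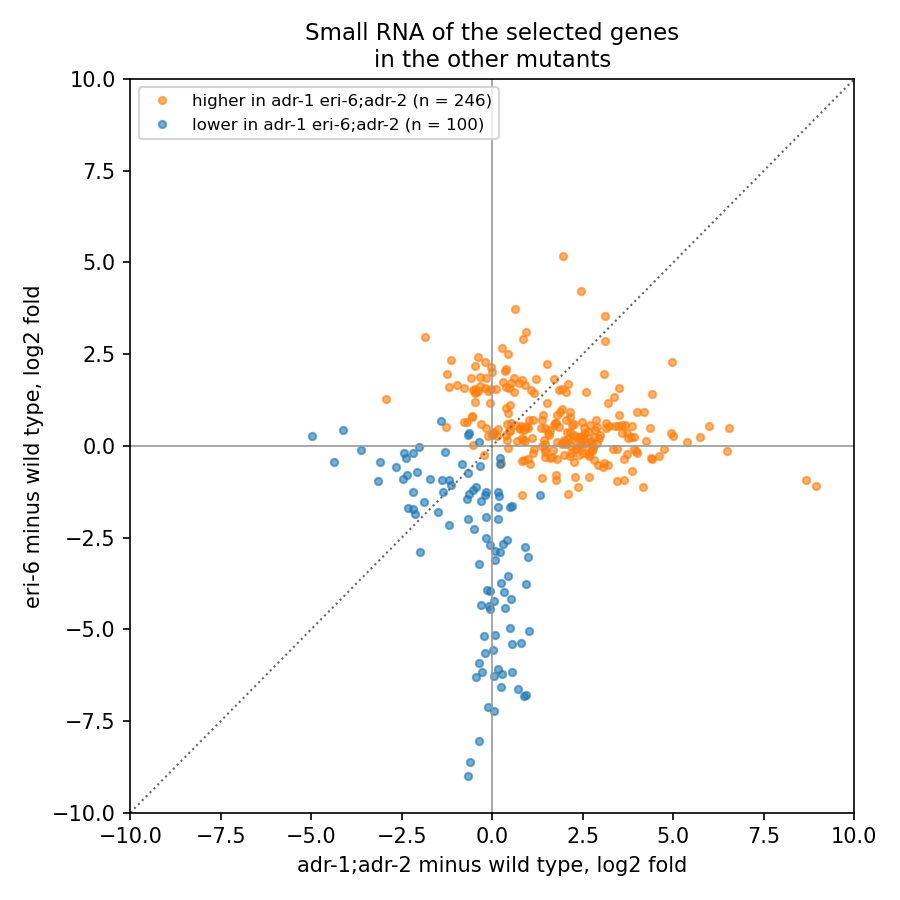
Log2 fold of normalised small RNA in adr-1;adr-2 (horizontal) and eri-6 (vertical) over wild type, for the genes selected in adr-1 eri-6;adr-2 that were tested in both tables. Points are genes, and the dotted line marks equal folds; the median was 1.81 and 0.42 for the 246 higher genes and −0.26 and −1.99 for the 100 lower genes.

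Across all genes the small RNA folds of adr-1;adr-2 and eri-6 were compared with a simulation of 100 draws. In it unchanged mutants shared simulated wild-type libraries. The correlation across genes was 0.428 against a simulated 0.499, and the covariance was 0.337 against a simulated 0.210, an excess of 0.126. The same sign was found for 74.6% of genes against a simulated 66.6%. Genes apart by 4-fold in both mutants numbered 0 on the high side (0.119 expected from independence, 0.450 simulated) and 0 on the low side (0.0665 and 0.880). With DESeq2 calls there were 0 and 1. Genes are not independent replicates. The simulated values hold shared wild-type libraries and no effects, with 1 spread per gene for all genotypes. Wild-type replicates correlated by 0.691, against 0.741 for adr-1;adr-2 and 0.773 for eri-6. A larger spread in wild type would raise the covariance, so the excess cannot be read as shared effects. The wild type was not split, because each part would hold 1 library.

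Total RNA showed how the transcripts themselves differed. The eri-6 transcript (WBGene00016561, I:4457375-4469458) fell from 17.8 FPKM in wild type to 5.35 in eri-6 and 5.73 in adr-1 eri-6;adr-2, and it was 10.1 in adr-1;adr-2 with overlapping bounds. The adjacent eri-7 gene (WBGene00016566, I:4451194-4456805) rose from 3.39 to 10.1 in eri-6, 20.8 in adr-1;adr-2 and 18.0 in adr-1 eri-6;adr-2. The RIG-I related gene drh-1 (WBGene00001090, IV:6607376-6613353) rose from 5.84 to 15.8 in adr-1;adr-2 and 16.04 in adr-1 eri-6;adr-2, and was 8.51 in eri-6 with overlapping bounds. Likewise nrde-3 (WBGene00019862, X:372235-376900) rose from 1.67 to 3.90 and 4.92, and was 2.18 in eri-6 with overlapping bounds. No value could be used for adr-1 or adr-2 here.

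Large parts of the transcriptome differed between these genotypes. In adr-1;adr-2, 2550 genes were higher and 1717 lower than wild type of 17666 listed above 0, of which 2233 and 1315 were protein-coding. In eri-6 the numbers were 1477 and 848 of 16866, of which 1137 and 514 were protein-coding, and in adr-1 eri-6;adr-2 they were 2601 and 2119 of 16761, of which 2274 and 1676 were protein-coding. The median log2 fold of genes at 5 FPKM or more was −0.06, 0.05 and −0.04. Fewer genes separated the mutants that lack both adr genes, with 345 higher and 501 lower in adr-1 eri-6;adr-2 than in adr-1;adr-2. Against eri-6, adr-1 eri-6;adr-2 had 1144 higher and 1510 lower, and adr-1;adr-2 had 1247 higher and 1052 lower. Of the genes higher in adr-1;adr-2, 1938 were also higher in adr-1 eri-6;adr-2 (352 expected from independence) and 911 in eri-6 (200 expected); lower genes gave 1560 (193 expected) and 712 (77.3 expected). Shared genes of eri-6 and adr-1 eri-6;adr-2 numbered 966 higher (204 expected) and 774 lower (95.4 expected). All these overlaps rest on the same wild-type libraries, which raise them by an amount that was not simulated. Wild type also stood apart in composition, with 9900 genes at 1 FPKM or more against 10732 in adr-1;adr-2, 10616 in eri-6 and 10372 in adr-1 eri-6;adr-2, and with an FPKM sum of 2.21e+07 against 3.93e+06, 8.05e+06 and 3.85e+06.

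Germline transcripts were the class that rose most clearly where adr-1 and adr-2 were lost. Of 21 oocyte and germline genes 19 rose and 0 fell in adr-1;adr-2, with a median log2 fold of 2.17 that lay at percentile 100. The oocyte maturation gene oma-1 (WBGene00003864, IV:8888976-8890999) rose from 2.93 to 23.9 FPKM, and cpg-1, spn-4 and puf-11 rose by 2.64, 2.59 and 2.53 on the log2 scale. The adr-1 eri-6;adr-2 mutant had 19 rising with a median of 2.02 (percentile 100), led by puf-11 at 2.73, and in eri-6 10 rose with a median of 0.65 (percentile 98.7). Without the wild-type value, adr-1;adr-2 lay above eri-6 for 13 of the 21 and below for 0, with a median of 1.23 (percentile 100). RNAi factors, many of which act in the germline, rose for 26 of 36 genes in adr-1;adr-2 with 1 falling (median 1.20, percentile 99.99). Among them rde-2, ego-1, rrf-3 and mut-2 lay at 2.57, 2.53, 2.53 and 2.43. Rises numbered 21 and falls 2 in adr-1 eri-6;adr-2 (median 1.15), and in eri-6 7 rose (median 0.36, percentile 87.8). Sperm genes had medians of 1.35, 1.23 and 1.41 in adr-1;adr-2, eri-6 and adr-1 eri-6;adr-2, with 25, 20 and 27 of 56 rising and 12, 9 and 12 falling. Collagen genes of the cuticle rose for 31 of 87 in adr-1;adr-2 with 6 falling (median 0.63), led by col-175 at 2.07 and col-139 at 2.02. They rose for 35 in adr-1 eri-6;adr-2 with 7 falling (median 0.43), while in eri-6 1 rose and 4 fell (median 0.08).

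Single intestinal transcripts and C-type lectin and antimicrobial genes went the other way in all 3 mutants. The cysteine protease gene cpr-1 (WBGene00000781, V:11975551-11976756) fell from 1204 FPKM to 26.7 in adr-1;adr-2, 140 in eri-6 and 46.1 in adr-1 eri-6;adr-2. The metallothionein gene mtl-2 (WBGene00003474, V:14018270-14018673) fell from 2213 to 72.1, 227 and 41.9, and the glutathione transferase gene gst-33 (WBGene00001781, V:3467451-3468562) from 79.7 to 1.36, 1.05 and 0.630. Of 13 intestine genes 10, 6 and 12 fell and 0 rose, with medians of −1.36, −0.83 and −1.68. Random lists of like expression were often low as well, and the intestine medians lay at percentiles 7.47, 2.61 and 5.71. C-type lectin and antimicrobial genes fell for 50, 24 and 58 of 97 and rose for 7, 3 and 4, with medians of −0.98, −0.36 and −1.41, all at percentile 0. Detoxification genes fell for 24, 16 and 46 of 114 and rose for 8, 12 and 6, with medians of −0.35, −0.17 and −0.74, also at percentile 0. Vitellogenin genes had medians of −0.37, −1.28 and −1.49 (percentiles 42.98, 0.15 and 5.92), with 0, 5 and 4 of 6 falling; vit-1 fell by 1.53 on the log2 scale in eri-6 and by 2.14 in adr-1 eri-6;adr-2. Ribosomal protein genes, which are very highly expressed, had medians of −0.996, −0.63 and −0.92, with 14, 3 and 11 of 65 falling and 0 rising. These medians nevertheless lay above those of most random lists of like expression, at percentiles 99.97, 85.7 and 100.

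**Figure D3:**
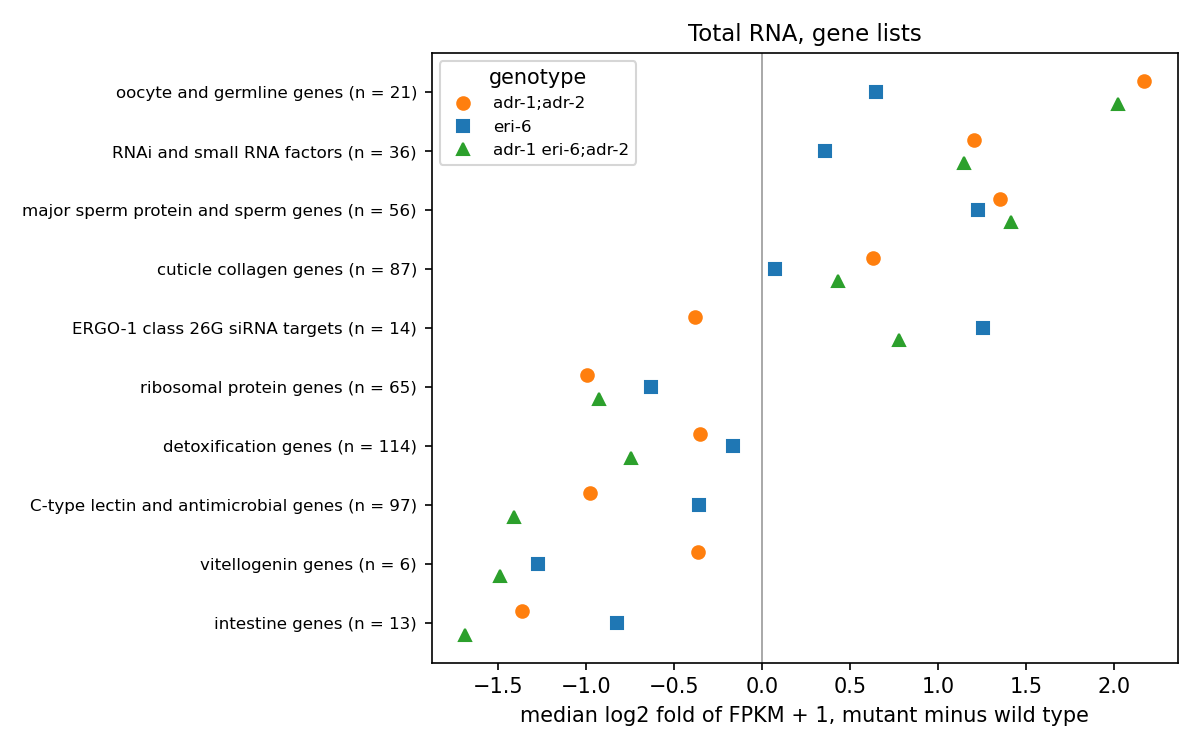
Median log2 fold of total RNA FPKM plus 1 over wild type for 10 gene lists in each mutant, with the number of genes per list in brackets. Each symbol is a median over genes from 1 value per genotype; the germline list lay at 2.17 in adr-1;adr-2 and the intestine list at −1.68 in adr-1 eri-6;adr-2.

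The ERGO-1 class responded to the loss of eri-6. Of 14 measured genes 6 rose and 0 fell in eri-6, with a median of 1.25 (percentile 99.99). The pseudogene E01G4.7 (WBGene00045410, II:13477471-13478929) rose from 5.09 to 36.5 FPKM, and F55C9.5, K02E2.6 and F55C9.3 rose by 2.36, 2.19 and 2.17 on the log2 scale. In adr-1;adr-2 0 rose and 3 fell, with a median of −0.38, and C44B11.6 and W04B5.1 lay at −2.85 and −2.22. In adr-1 eri-6;adr-2 2 rose and 1 fell, with a median of 0.78, while compared with adr-1;adr-2 7 rose and 0 fell, with a median of 1.39 (percentile 100). Against eri-6, 0 rose and 4 fell, with a median of −0.64.

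Stress and remaining classes were less uniform. The ER chaperone gene hsp-4 (WBGene00002008, II:7350119-7352518), a target of the unfolded protein response, rose from 52.3 to 248 FPKM in adr-1 eri-6;adr-2, and was 73.5 in adr-1;adr-2 and 56.5 in eri-6 with overlapping bounds. Over 12 unfolded protein response genes the medians were −0.51, −0.19 and −0.06 in adr-1;adr-2, eri-6 and adr-1 eri-6;adr-2. Pathogen response genes other than pals had medians of 0.44, 1.01 and 0.92 over 5 genes, and fbxa-182 and cul-6 rose by 1.28 and 1.16 in eri-6 and by 1.58 and 1.28 in adr-1 eri-6;adr-2. The 7 pals genes had −0.71, −0.09 and 0.05, the 36 histone genes −0.40, −0.03 and 0.07, and the 157 F-box genes 0.07, 0.30 and 0.02. Heat shock genes had 0.27, −0.01 and −0.20, muscle genes −0.12, −0.54 and −0.51, neuron genes 0.19, 0.03 and 0.02, and the 5 microRNA genes −1.14, −0.31 and −0.84.

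Single protein-coding genes with large folds, chosen by the rule added after seeing the data, included embryonic and defence genes. In adr-1;adr-2 F37C4.8 rose by 4.35, F02H6.3 by 3.60, ztf-15 by 3.29, nspd-1 by 3.14, and the embryonic polarity gene mex-5 from 5.72 to 58.5 FPKM. In eri-6 F48C1.9 (WBGene00018601, I:5332249-5332780) rose from 4.65 to 173 FPKM, nspd-1 by 3.62, far-3 by 2.74, coa-7 by 2.71 and fem-3 by 2.68. In adr-1 eri-6;adr-2 C38D9.2 (WBGene00008010, V:17567150-17571739) rose from 0.258 to 21.9 FPKM and Y41C4A.11 (WBGene00012757, III:11719861-11721077) from 12.5 to 212. F19B10.10 and C08E8.4 rose by 3.98 and 3.92 there, F22E5.6 by 3.49 and srp-7 by 3.19. F15D4.5, whose small RNA was low in both mutants that lack the adr genes, rose from 0.960 to 10.5 FPKM in adr-1;adr-2 and 20.4 in adr-1 eri-6;adr-2, and was 0.797 in eri-6. Beside cpr-1, mtl-2 and gst-33, large falls were those of nspc-18 at −4.66, C18B10.6 at −4.37 and cyp-33C2 at −4.33 in adr-1;adr-2. In eri-6 Y110A2AL.9 lay at −4.49, F08D12.2 at −4.31, ins-28 at −4.20 and asp-12 at −3.75. In adr-1 eri-6;adr-2 F08D12.2 lay at −5.72, asp-12 at −4.95, ilys-5 at −4.85 and cyp-35A3 at −4.52. The rule fixed earlier named mostly short RNA loci listed at 0 in 1 genotype, such as MTCE.24 and Y41D4B.35 on the high side and F54C4.6 and Y17D7B.10 on the low side in adr-1;adr-2.

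Small RNA and total RNA were then joined gene by gene, to ask whether a gain or loss of siRNA went with a difference of the transcript. Genes with less small RNA in eri-6 had more transcript by their median, though most of those measured had overlapping bounds. Of the 136 genes 4-fold lower in small RNA, 60 were measured in total RNA, and 23 rose, 1 fell and 36 had overlapping bounds, with a median of 0.80 (percentile 100). Genes with more small RNA in adr-1;adr-2 had a median of −0.52 over 58 measured (percentile 0.08), with 4 rising, 15 falling and 39 with overlapping bounds. With the genes called by DESeq2 in place of the 4-fold rule the median was −0.25 over 48 measured (percentile 2.89), with 6 rising and 9 falling. The few genes with less small RNA in adr-1;adr-2 had a median of 1.16 over 7 measured, with 3 rising and 0 falling (percentile 97.6). With DESeq2 calls that direction turned, to a median of −0.11 over 4 measured with 2 rising and 1 falling. Among the selected genes past 0.05, those with more small RNA in adr-1 eri-6;adr-2 had a median of −1.06 over 199 measured, with 33 rising and 97 falling (percentile 0). Those with less small RNA had a median of 0.69 over 40 measured, with 13 rising and 10 falling (percentile 99.6). C-type lectin genes, which fell in total RNA as a class, and the intestine genes pept-1 and lys-1 were also among the selected genes with more small RNA. The sets from limma planned for adr-1;adr-2 and eri-6 were empty, so the sets used here were chosen after seeing the data.

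Messenger RNA was measured under RNAi to ask which responses of adr-1 eri-6;adr-2 need drh-1 or nrde-3. The targeted genes were examined first. The drh-1 transcript was higher, not lower, in the libraries labelled drh-1 RNAi, at 32.3 FPKM against 14.3 on control in wild type and 65.4 against 19.0 in adr-1 eri-6;adr-2. Its neighbour drh-2 (IV:6613918-6618498) was lower there, at 1.72 against 2.80 and 1.30 against 7.45. Also lower were eri-7, at 11.5 against 30.2 and 2.96 against 17.7, and eri-6, at 7.77 against 13.8 and 3.68 against 7.10. The adr-1 gene, at 31.4 against 23.8 and 18.6 against 17.7, was not lower. The nrde-3 transcript in the libraries labelled nrde-3 RNAi was 5.26 against 5.76 in wild type and 8.08 against 15.4 in adr-1 eri-6;adr-2. FPKM per gene cannot separate reads of the transcript from reads of double-stranded RNA made in the bacterial food.

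**Figure D4:**
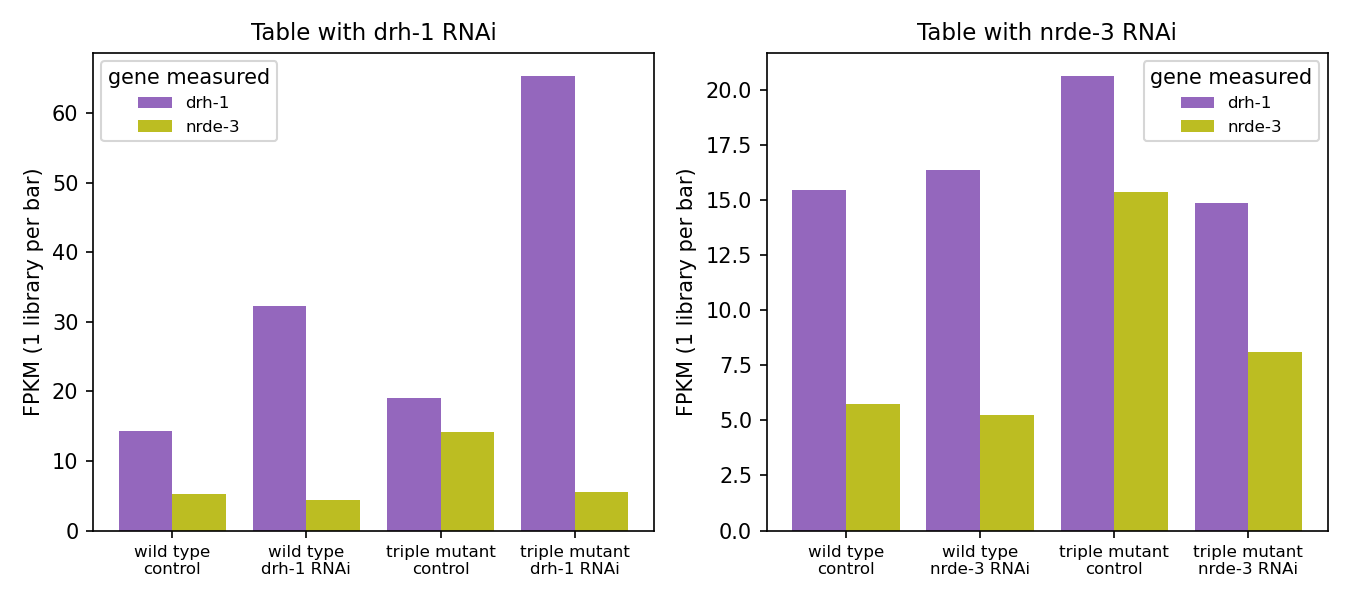
FPKM of drh-1 and nrde-3 in each mRNA library, 1 library per bar, in the tables made with the drh-1 and nrde-3 RNAi libraries; the triple mutant is adr-1 eri-6;adr-2. In the table of libraries labelled drh-1 RNAi, drh-1 stood at 14.3 and 32.3 in wild type and 19.0 and 65.4 in the mutant.

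On control RNAi the adr-1 eri-6;adr-2 mutant again had far higher levels of a few genes. With 1 library per condition there is no spread, and a gene counts as different at a 4-fold size alone. F48C1.9 stood at 163 FPKM against 1.09 in wild type, Y41C4A.11 at 255 against 7.00, F15D4.5 at 47.3 against 1.46, the antimicrobial peptide gene nlp-34 at 340.2 against 14.1 and sea-2 (II:3950377-3972140) at 189 against 1.16. Next came sdz-35 at 4.68 on the log2 scale, C18D11.6 at 4.58, F22E5.6 at 4.34, grk-1 at 4.29 and srlf-34 at 4.16. On the low side pud-4 (WBGene00017498, V:2326678-2327282) stood at 14.3 against 304 FPKM, with its neighbour pud-3 at −4.11, laf-1 at −5.19, Y67H2A.10 at −4.95, Y44A6D.7 at −4.79, D1054.18 at −3.65 and asp-13 at −3.61. In total 401 genes were at least 4-fold higher and 213 lower, of which 227 and 96 were protein-coding, and 210 and 110 were listed at 0 on the other side. The scaling of the nrde-3 table gave 435 and 220. The rule fixed earlier named short loci such as R04E5.15, F14B6.8 and Y24D9A.10, listed at 0 in wild type. Of the 401 genes, 63 were also at least 4-fold higher in total RNA of that genotype (6.18 expected).

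Gene classes on control RNAi partly followed total RNA. Medians are given beside a shift of −0.24 over all genes at 5 FPKM or more. Sperm genes had a median of 1.88, with 26 of 59 at least 4-fold higher, collagen genes 0.76, germline genes 0.57 (percentile 100) and RNAi factors 0.31. ERGO-1 class genes had 0.88 (percentile 99.9), led by F55C9.3 at 3.32 and F55C9.5 at 3.29. Pathogen response genes other than pals had 0.77, with fbxa-158 at 2.09 and skr-5 at 2.02. Vitellogenin genes had −1.02, detoxification genes −0.59, F-box genes −0.45, ribosomal protein genes −0.42, C-type lectin genes −0.39, intestine genes −0.39 and pals genes −0.36. Muscle genes had 0.59, unfolded protein response genes 0.35, neuron genes 0.18, heat shock genes −0.15 and the 2 microRNA genes 1.83. Histone genes had −0.13, which became 0.11 when the libraries were rescaled to the same median.

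In the libraries labelled drh-1 RNAi, few protein-coding genes departed from control in wild type, where 133 genes were 4-fold higher and 147 lower, of which 29 and 28 were protein-coding. These included gyf-1 at 5.47, F01E11.18 at 5.17, C07E3.3 at 4.92, sea-2 at 4.45 and grk-1 at 4.34 on the high side and Y67H2A.10 at −6.44, Y54G2A.28 at −3.37 and egrh-2 at −2.96 on the low side. The mutant adr-1 eri-6;adr-2 had 142 higher and 391 lower genes, of which 41 and 215 were protein-coding. There Y67H2A.10 stood at 5.40, W02A2.8 at 3.06 and egl-30 at 2.91, and sea-2 at −5.12, C23H5.11 at −5.09, B0511.12 at −3.92, grk-1 at −3.85 and rad-50 at −3.84. Genes such as sea-2, grk-1 and Y67H2A.10 thus took opposite directions in both genotypes. Each direction rests on 1 control library per genotype, which also served the nrde-3 comparison. Under the nrde-3 label sea-2 likewise rose in wild type and fell in the mutant. A response to drh-1 RNAi therefore cannot be told apart from the values of those control libraries. Vitellogenin genes had medians of 1.47 in wild type and 1.61 in adr-1 eri-6;adr-2, muscle genes 1.23 and 1.10, ribosomal protein genes 0.63 and 0.95, collagen genes 0.86 and 0.36 and intestine genes 0.43 and 0.74, beside shifts of −0.18 and 0.13 over all genes.

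The other lists were also followed under the drh-1 label, and some moved as far as those above. In wild type and adr-1 eri-6;adr-2 respectively, ERGO-1 class genes had medians of −0.30 and 0.27, sperm genes 0.35 and 0.43, histone genes 0.45 and 0.28, C-type lectin genes 0.15 and 0.38, heat shock genes 0.16 and 0.44, detoxification genes −0.40 and −0.02, and RNAi factors −0.22 and −0.29. Germline genes had 0.05 and −0.25, pathogen response genes other than pals 0.03 and 0.12, pals genes −0.22 and 0.09, unfolded protein response genes 0.14 and 0.09, neuron genes −0.18 and −0.24, and the microRNA genes 0.27 and 0.81. F-box genes had −0.34 and 0.06, the second of which became −0.02 when the libraries were rescaled.

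In the libraries labelled nrde-3 RNAi, wild type had 173 genes 4-fold higher and 144 lower than on control, of which 38 and 29 were protein-coding. Among them were sea-2 at 5.05, F01E11.18 at 4.97, gyf-1 at 4.80, Y67H2A.10 at −6.01 and C23H5.11 at −4.81. In adr-1 eri-6;adr-2 148 were higher and 231 lower, with F37C4.8 at 7.15, D1054.18 at 3.71, sea-2 at −5.92, grk-1 at −3.99 and C02E7.7 at −3.40. The ERGO-1 class medians were 0.28 in wild type and 0.58 in adr-1 eri-6;adr-2, beside shifts of −0.12 and 0.18 over all genes. Germline genes had −0.86 in adr-1 eri-6;adr-2, sperm genes −0.49, collagen genes −0.32 and RNAi factors −0.26, whereas vitellogenin genes had 1.05, intestine genes 0.66, pals genes 0.61, F-box genes 0.58, ribosomal protein genes 0.51, C-type lectin genes 0.47, detoxification genes 0.46, unfolded protein response genes 0.33, pathogen response genes other than pals 0.30, histone genes 0.21, heat shock genes 0.14, muscle genes 0.11 and neuron genes −0.01. In wild type the microRNA genes had 0.89, and the lists other than these and the ERGO-1 class had medians between −0.30 for germline genes and 0.22 for pathogen response genes other than pals.

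The genes raised at least 4-fold in that mutant on control were then followed under RNAi. Of 401 such genes 383 were at 1 FPKM or more. In the library labelled drh-1 RNAi their median in the mutant was −0.90 against control, with 140 at least 4-fold lower and 4 higher, and in wild type it was 0.16. Under the nrde-3 label 419 genes had a median of −1.35, with 148 at least 4-fold lower. The genes lowered on control had medians of 0.72 and 1.13 in the mutant under these labels. In wild type the same genes had −1.31 with 90 of 210 at least 4-fold lower, and −0.96 with 94 of 215 lower. A set chosen on 1 control library tends to return toward the middle in any other library. The set chosen on total RNA alone had a median of −0.40 over 375 measured genes in the mutant under the drh-1 label. Of these, 56 were at least 4-fold lower and 11 higher. In wild type the same genes had a median of −0.41, with 12 lower and 12 higher. Rescaled to the same median ratio, the medians were −0.52 in the mutant and −0.23 in wild type. Under the nrde-3 label 372 such genes had −0.37 in the mutant, with 16 lower and 8 higher, and −0.07 in wild type. The 62 measured genes raised in both total RNA and on control, which were thus still chosen in part on the control library, had a median of −0.005 under the drh-1 label with 10 at least 4-fold lower, and 64 such genes had −0.56 under the nrde-3 label with 11 lower. Y41C4A.11, sdz-35, F22E5.6 and C38D9.2 remained high in the mutant over wild type, at 6.51, 5.26, 4.75 and 4.15 under the drh-1 label and 7.38, 6.49, 5.89 and 4.90 under the nrde-3 label.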

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

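The tests of explanations in this part were all chosen after the results they measure had been seen, and the genes and lists were picked out by a fixed rule on opposite directions.

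In total RNA, some genes responded to the loss of eri-6 in 1 direction on the wild-type background and in the other direction where adr-1 and adr-2 were already lost. The differences were not tested, because each genotype has 1 deposited value with bounds. A protein-coding case was pud-4 (WBGene00017498, V:2326678-2327282), a gene of a small cluster named after protein levels raised in dpy mutants. Loss of eri-6 moved pud-4 by 2.08 on the log2 scale on the wild-type background and by −2.37 on the other. Loss of adr-1 and adr-2 moved it by 2.31 on the wild-type background and by −2.14 on the eri-6 background. Its FPKM was 4.71 in wild type, 27.2 in adr-1;adr-2, 23.1 in eri-6 and 4.47 in adr-1 eri-6;adr-2. In mRNA on control, however, pud-4 stood at 304 FPKM in wild type against 14.3 in adr-1 eri-6;adr-2, so the near equality of these genotypes was not seen there. F43G9.21 (I:8616392-8616948) moved by 2.70 and −2.64 on loss of eri-6 and by 2.64 and −2.70 on loss of the adr genes, and it was listed at 0 in wild type and adr-1 eri-6;adr-2.

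Other genes of this kind included loci both short and long. C05A2.4 (V:10695481-10695612), a locus of 132 bp, moved by 3.60 and −3.16 on loss of eri-6 and by 3.16 and −3.60 on loss of the adr genes. T12G3.11 (IV:12029704-12029772), a locus of 69 bp, moved by 7.24 and −6.24 and by 6.24 and −7.24. Y66H1A.8 (IV:451118-454916), a locus of 3799 bp, moved by 8.88 and −5.23 on loss of eri-6 and by 8.59 and −5.52 on loss of the adr genes, with 384 FPKM in adr-1;adr-2 and 470 in eri-6 against 9.27 in adr-1 eri-6;adr-2. The reverse order was seen for C16C4.17 (II:1864578-1864884), which moved by −2.34 on loss of the adr genes in wild type and by 2.57 in eri-6. In all, 40 genes rose on loss of eri-6 in wild type and fell on its loss in adr-1;adr-2, of which 12 were protein-coding, and 23 did the reverse, of which 4 were protein-coding. For loss of the adr genes the numbers were 55 with 26 protein-coding and 23 with 4 protein-coding. These differences were not tested, and no expected number by chance was computed.

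The mitochondrial and ER unfolded protein response genes were picked out as a list. Their median was −0.51 for loss of the adr genes in wild type, with 3 lower, 2 higher and 7 with overlapping bounds, and 0.64 for the same loss in eri-6. The first value was ordinary for random lists of like expression (percentile 27.9) and the second was not (percentile 99.93), so the fall is not supported. The difference was not tested, and the adr-1;adr-2 and adr-1 eri-6;adr-2 total RNA labels name different adr alleles, although the strain name given for adr-1;adr-2 would make them the same.

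The first pattern weighed was that genes selected for high small RNA in adr-1 eri-6;adr-2 were also high in adr-1;adr-2, while those selected for low small RNA were also low in eri-6. The same wild-type libraries in every comparison could make mutants look alike, but the wild type drops out when eri-6 is set against adr-1;adr-2 directly. That median was −1.36 for the higher genes and −1.98 for the lower genes, which argues against it for both sets. BB4 and BB21 are labelled with different alleles, and the smaller of both adr-1;adr-2 library medians for the higher genes was 1.56. This argues against a variant in the background of 1 of the 2 adr-1;adr-2 strains. Both medians are raised by the wild-type libraries, on which the genes were selected. The eri-6 median over the same wild-type libraries was 0.42, below both. Separate action of the adr genes and eri-6 on these sets stays a hypothesis, and the genes were chosen by the authors on libraries of the same series.

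The second pattern was the rise of germline transcripts in adr-1;adr-2 total RNA. A single scaling factor per genotype is argued against by the median of −0.0614 over all genes at 5 FPKM or more. A larger share of germline against all somatic tissue, as the only difference, would lower every somatic class alike. These moved apart, with 31 of 87 collagen genes rising and 6 falling while 10 of 13 intestine genes fell. Random lists with expression like that of the intestine genes were often low as well, so the intestine fall weighs little here. The collagen rises argue against such a share as the sole difference, but cannot decide on it beside a difference in stage. Wild type stood apart from all mutants in composition, but adr-1;adr-2 against eri-6, with no wild-type value, kept a median of 1.23. A smaller share of intestine alone and an effect of lost editing were not tested, and a difference in the stage of the cultures cannot be told apart from genotype, because vitellogenin genes with bounds apart numbered 0 and both libraries of a genotype share 1 value.

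The third pattern was the higher drh-1 signal in the libraries labelled drh-1 RNAi. If control and drh-1 RNAi libraries had been swapped, the control would be low next to nrde-3 RNAi libraries, but the larger ratio of drh-1 in an nrde-3 RNAi library over control was 1.06. Reads of the RNA trigger taken up from the bacteria cannot be told apart from transcript, since 32.3 FPKM in wild type is a sum over the gene. A true rise of the transcript was not tested.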

How the results depend on the processing

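The counts of protein-coding genes alone, the fit of all 6 libraries, DESeq2 and edgeR with the replicate number, and the sets of genes that were separated or called by DESeq2 were chosen after seeing the data, and the other alternatives were chosen before.

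Small RNA counts depended on the test and the filter. In adr-1;adr-2 limma called 0 genes higher, against 2 with a pseudocount of 10, 37 with a mean value of at least 50, 41 with TMM scaling, 31 with equal totals and 108 with DESeq2. Lower genes numbered 0, against 30 with a mean value of at least 50, 8 with TMM scaling, 6 with equal totals and 10 with DESeq2. In eri-6 higher genes numbered 0, against 4 with a mean value of at least 50, 2 with equal totals and 15 with DESeq2. Lower genes numbered 0, against 68 with a mean value of at least 50, 74 with equal totals, 125 with DESeq2 and 24 with 1 fit of all 6 libraries. A higher minimum tests fewer genes, and the cause of the other moves was not tested. With a replicate block in limma, eri-6 had 8 genes higher and 98 lower, adr-1;adr-2 had 0 and 0, and adr-1 eri-6;adr-2 had 239 and 81 of the selected genes. With a replicate block in DESeq2 the numbers were 175 and 50 for adr-1;adr-2 and 35 and 159 for eri-6, while edgeR with a replicate block called 0 and 0 in both. On simulated data with the observed replicate difference, limma with the block recovered 97 of 100 genes changed 4-fold for adr-1;adr-2 and 95 for eri-6, with 14 and 16 unchanged genes called. The simulated noise was a fixed dispersion not estimated from these libraries. These numbers are thus no measure of recovery in the real data, where limma with the block called 0 and 0 in adr-1;adr-2. In 1 fit of 6 libraries, 12 histone genes were lower in eri-6 than in adr-1;adr-2 with the block and 0 without it. Whether replicate numbers pair the libraries is not stated in the labels; differences between replicates 1 and 2 correlated by 0.5998 for adr-1;adr-2 with wild type, 0.680 for eri-6 and 0.133 for the selected genes.

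Leaving out 1 library leaves 1 sample in its group, which limma assumes to vary like the other group. Higher genes then numbered 3 to 32 and lower genes 0 to 49 in adr-1;adr-2, and 0 to 11 and 42 to 90 in eri-6. Higher selected genes in adr-1 eri-6;adr-2 went from 245 to between 127 and 213. The cause was not tested.

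For gene lists, 0 of the 12 lists that passed in adr-1;adr-2 and 0 of the 8 in eri-6 passed with the correlation estimated or with fry. The histone list in adr-1;adr-2 had adjusted p = 0.721 with the correlation estimated and 0.482 with fry, and the ERGO-1 class in eri-6 had adjusted p = 0.389 and 0.172. Both tests lower the certainty by construction where list members vary together. Leaving out 1 library gave 9 to 13 lists in eri-6. The histone list in adr-1;adr-2 and the ERGO-1 class in eri-6 kept their direction and passed without each of the 4 libraries in turn.

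Several lists changed direction when 1 library was left out, which also leaves unequal numbers of replicates 1 and 2 and so is no measure of stability. In adr-1;adr-2 the adjusted p then ranged over 0.00206 to 0.942 for collagen, 9.89e-05 to 0.179 for ERGO-1 class, 6.38e-06 to 0.0825 for F-box, 4.88e-35 to 0.000258 for sperm and 0.000118 to 0.760 for microRNA genes. It ranged over 0.00289 to 0.757 for unfolded protein response, 0.000182 to 0.942 for germline, 1.68e-45 to 0.285 for piRNA and 4.00e-06 to 0.942 for RNAi factor genes. In eri-6 it ranged over 0.00294 to 0.00998 for collagen, 2.17e-06 to 0.000451 for F-box, 0.0176 to 0.178 for heat shock, 9.95e-05 to 0.0151 for histone and 1.42e-37 to 0.259 for sperm genes. It ranged over 0.00342 to 0.805 for unfolded protein response, 9.09e-05 to 0.9998 for germline, 2.86e-75 to 0.0165 for piRNA and 4.93e-05 to 0.529 for RNAi factor genes.

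In mRNA the counts followed the threshold and the pseudocount, since no test stands behind them. For the mutant against wild type on control, higher genes went from 401 to 1361 with a pseudocount of 0.1, 1454 at a fold of at least 2 and 227 for protein-coding genes, and lower genes from 213 to 462, 1968 and 96. Under the drh-1 label in wild type the same settings gave 420, 444 and 29 higher and 367, 1166 and 28 lower genes. Under that label in the mutant they gave 308, 837 and 41 higher and 1106, 1429 and 215 lower. For nrde-3 RNAi they gave 496, 391 and 38 higher and 335, 284 and 29 lower genes in wild type, and 385, 1509 and 36 higher and 787, 925 and 81 lower in the mutant. In total RNA, lower genes in eri-6 went from 848 to 514 with protein-coding genes alone.

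The F-box median under the drh-1 label in the mutant turned from 0.06 to −0.0195 when libraries were rescaled to the same median ratio. The genes raised in the mutant on control went from −0.90 to −1.01 with a pseudocount of 0.1 and −1.01 rescaled under the drh-1 label, and from −1.35 to −1.56 and −1.49 for nrde-3 RNAi. Genes with more small RNA in adr-1;adr-2 had a total RNA median of −0.25 if called by DESeq2, and those with less small RNA turned from 1.16 to −0.113. With a pseudocount of 0.1 the ERGO-1 class median was −0.74 in adr-1;adr-2 and 1.85 in eri-6, and the genes with less small RNA in eri-6 had 1.02. Genes lower in both mutants numbered 1 with DESeq2 and 0 otherwise. The cause was not tested.

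Of all 370 small RNA list values under alternatives, 263 kept their direction and side of the threshold, 55 fell short of it, 23 newly passed and 29 changed direction. Of 2589 values for named small RNA genes, 2221 were kept, 298 newly passed and 70 moved. None of these genes passed in the main fit, so none could fall short. A value was kept when its sign held and it did not newly pass, which is a weak measure of stability. Of 237 FPKM list values 168 were kept, and of 336 for FPKM genes and sets 324 were kept. For the named FPKM genes this was fixed in advance and is no measure of stability. Calls in total RNA do not use the pseudocount, and the smaller pseudocount can only enlarge a fold in mRNA. A q-value of 0.01 in total RNA was not run, because no q-value was in the table, nor were the authors' adjusted p for small RNA. TMM scaling, equal totals, edgeR and DESeq2 were not run on the selected genes of adr-1 eri-6;adr-2, whose full libraries were not analysed here. Depth limits what small RNA can show for genes with few reads, since the shallowest library held 10904105 reads.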

Other observations

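The loci in this part and the use of bounds in total RNA were chosen after the results were seen, and the limma test was chosen before.

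The F15D4.5 locus (WBGene00008862, II:13245376-13247774) joined small RNA and transcript in opposite directions. In wild type it carried 27736 ± 19198 normalised small RNA reads (mean ± SD, n = 2), and in adr-1;adr-2 1805 ± 53.9. Among the selected genes of adr-1 eri-6;adr-2 it had 2427 against 32725 (adjusted p = 0.00243). Its total RNA stood at 0.960 FPKM in wild type, 10.5 in adr-1;adr-2, 0.797 in eri-6 and 20.4 in adr-1 eri-6;adr-2. In mRNA on control it was 47.3 FPKM in adr-1 eri-6;adr-2 against 1.46 in wild type. This locus was singled out after its values were seen, and no link between its small RNA and its transcript was tested.

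The pmp-2 gene (WBGene00004059, II:6884040-6887805) had more small RNA in adr-1;adr-2, at 789 ± 216 against 8.33 ± 4.22, while its transcript was not called lower there. Its total RNA log2 fold was −0.08 in adr-1;adr-2 and 0.72 in eri-6, both with overlapping bounds, and it fell by 0.87 in adr-1 eri-6;adr-2. It too was singled out after its values were seen.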
